A study of Mus musculus with 32 samples.

How the data were processed

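Total RNA of mouse liver was labelled with biotin and hybridised to bead arrays, with 1 array per sample and 32 arrays in all. Females and males were run on different versions of the array, so levels cannot be set against each other between the sexes, and each sex was normalised and fitted on its own. The intensity values of each probe are background-subtracted and not normalised between arrays in the deposited tables used for the main results. A detection p-value for each probe and array is also deposited, per the file headers. A second deposited table holds intensity values that, from their shared quantiles, were quantile normalised on a linear scale; its medians per array were 13.5 to 13.6 in females and 8.58 to 8.65 in males. BeadStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here.

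Probes were named from the platform annotation. On the female version 23978 of 25697 probes had 1 gene symbol, 0 had several and 1719 none; on the male version 20984 of 24613 had 1, 1 had several and 3628 none. Values were background corrected and quantile normalised with neqc in limma 3.58.1 under R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 4 of 16 arrays of the sex were kept, which left 12561 in females and 12173 in males. For each gene the probe with the highest mean was tested, and probes without a single gene stayed as features of their own. This gave 8711 named and 735 unnamed features in females, and 8840 and 1457 in males. Over the features tested, the median of each normalised array lay within 0.0315 (log2) of the middle array median in females and within 0.0599 in males. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

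The 4 groups of a sex were fitted together with limma (lmFit and eBayes with an intensity trend), so that they shared 1 estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All limma tests were two-sided. The labels describe the arrays of a group as biological replicates, 4 per group, and this number limits the precision. Litter is not in the labels, so siblings within a group cannot be recognised. All limma tests treated the arrays as independent, those of the high-fat diet as well as those of the maternal diet and of the interaction. Their p-values may be too small if a group holds siblings. The comparison between the sexes set the male effect against the female effect over genes measured on both versions, of which 4686 of 6941 shared the probe. A probe detected on 0 arrays of the dimmer group has only a bound: its fold is given as at least the ratio of the brighter group's mean to the mean of, per array, the higher of the lowest detected signal and the probe's own value, all on normalised log2 values. Where it was detected on only 1 array of the dimmer group, the other arrays were treated in the same way and that array kept its value; with 2 or 3 such arrays the change is given with their number.

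Gene lists for pathways, for sex-biased liver expression and for other cell types were written down in advance. They were tested with camera at its preset correlation of 0.01, over lists with at least 3 measured genes, and again with an estimated correlation; fry was run beside it. Members were also counted after adjustment over the list alone. Camera made 90 calls over the comparisons described, and 0 of these passed with an estimated correlation. The high-fat effect averaged over maternal diets was also fitted and is not described further. For it limma called 829 genes and unnamed probes in females and 212 in males. Camera called 10 lists in each sex for it, of which 0 in females and 1 in males passed with an estimated correlation. Lists share some genes, so their tests are not independent.

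The genes named were set by a rule. For a comparison of groups these were the 6 largest rises and 6 largest falls among genes past the threshold whose 4 values in a group all lay on 1 side of the others, or else the 3 smallest p-values. Up to 3 members past the threshold were added from each list that camera called. For the offspring diet Cd36, Cyp4a14, Fasn and Scd1 were always looked up, and for the maternal diet Nr1h3, Ppara, Pck1 and Cyp7a1; some items of the rule are not reported here. For interactions and sex differences up to 5 genes past the threshold or the 3 smallest p-values were named. Other members of lists or overlaps that are named, such as Slc25a1, Plin2, Pparg, Anxa2, Lamb3 and Pdia5, were chosen after their values were seen.

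The procedure was tested on simulated data with 200 changed genes. Of 67 genes changed by 1 log2 unit, high-fat comparisons recovered 58 and 64 in females and 59 and 50 in males, and the interactions recovered 47 in females and 40 in males. Of 67 changed by 0.5, the interactions recovered 8 and 11. These numbers hold for 200 changed genes, and with fewer the adjusted threshold is harder to pass. In 12 simulations of a shifted list camera called the list 12 times, and 1 of 378 lists without a shift. The simulated genes varied independently of each other. This therefore does not give the rate of false list calls among genes that vary together.

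The grouping, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives fixed then were another normalisation, the deposited normalised values, no filter, a stricter filter, all probes, the arrays of the compared groups alone, array weights, the replicate number as a block, and each array left out in turn. A covariate for raw intensity, a covariate for the phase of the clock genes, the omission of the 4 dimmest female arrays, and the list calls and bounds with each array left out were chosen after seeing the data. Slide was not used as a block, since the columns used here do not give it. Coordinates and genome sequence were not used here.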

Results

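Gene expression was measured in liver of C57bl/6J OlaHsd mice at 20 weeks of age. Their mothers had received either a diet labelled 18%, the control, or a low-protein diet labelled 9%, with 90 g casein per kg, during gestation. From 6 weeks of age the offspring received a high-fat diet, with a fat content given as 36%, or a control diet for 14 weeks. Each of the 8 combinations of sex, maternal diet and offspring diet held 4 arrays, 32 in all, described as biological replicates. The title names the question as whether maternal protein restriction programmes glucose and fatty acid metabolism differently in the sexes. Females and males were hybridised to different versions of a mouse bead array, so each sex was normalised and tested separately. On the female arrays 44.0% to 47.3% of probes were detected above background, and on the male arrays 43.7% to 47.2%.

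The sex labels matched the arrays. Both probes for Xist, the RNA that silences an X chromosome in females, were detected on 16 of 16 female arrays. Eif2s3y, a gene of the Y chromosome, was detected on 0 of 16 female and 16 of 16 male arrays, with a mean log2 intensity of 9.27 ± 0.20 (SD, n = 16) in males. No probe was named Ddx3y on either version, and none was named Xist on the male version.

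Mean raw intensity differed between female groups. It was 423 ± 22.0 and 385 ± 44.5 units (SD, n = 4) in control and high-fat females of mothers on 18%, and 422 ± 43.9 and 343 ± 48.9 units in those of mothers on 9%. The 4 dimmest female arrays, at 300.0 to 349 units, were all high-fat arrays, and 3 of them came from offspring of mothers on 9%. In males it was 267 ± 14.8 and 245 ± 56.8 units in control and high-fat offspring of mothers on 18%, and 278 ± 20.9 and 252 ± 26.0 units in those of mothers on 9%. The high-fat means were thus lower than the control means in males as well. The dimmest male array, high-fat replicate 3 after 18%, stood at 170 units.

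**Figure D1:**
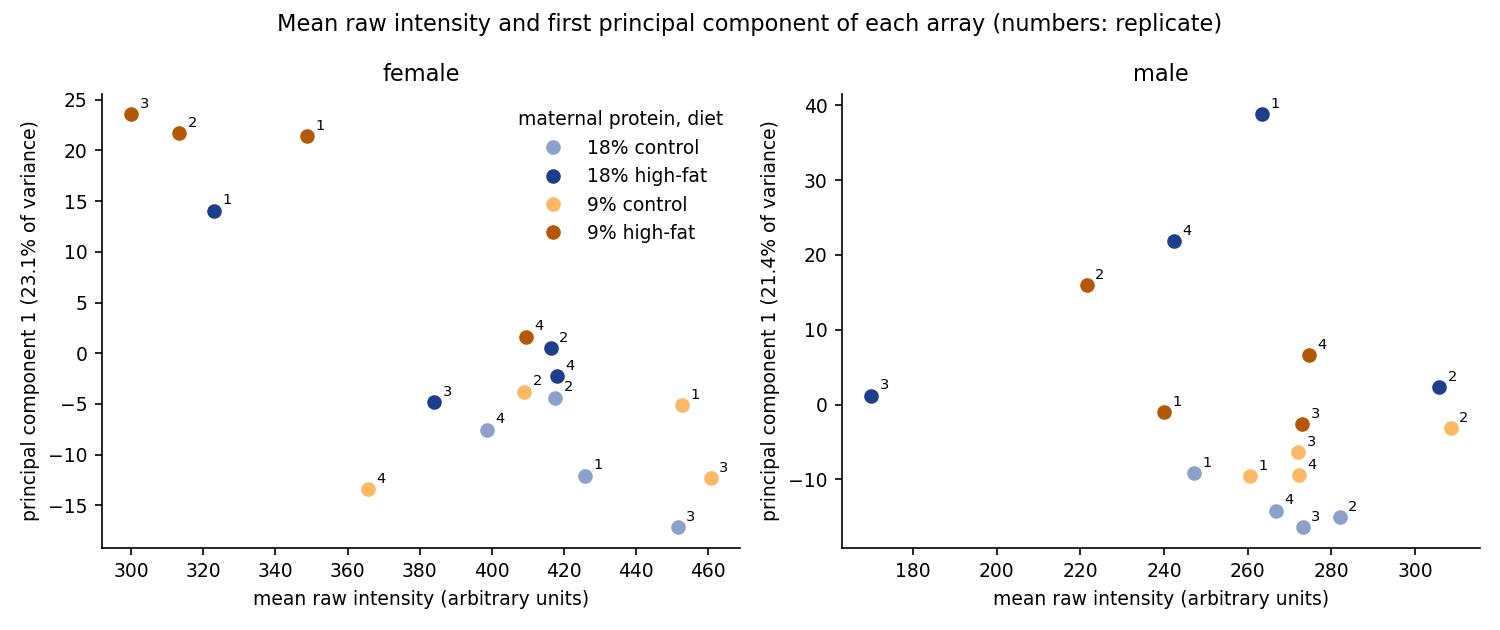
Mean raw intensity of each array in arbitrary units (x axis) against its first principal component (y axis), for 16 female arrays on the left and 16 male arrays on the right, coloured by maternal protein and offspring diet and numbered by replicate. Among female high-fat arrays of mothers on 9%, replicates 1 to 3 lie between 21.4 and 23.6 on the component and replicate 4 at 1.64.

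The first comparison asked what the high-fat diet did in females of mothers on 18%. Of 9446 genes and unnamed probes tested, 6 rose and 2 fell. Pltp, which transfers phospholipids between lipoproteins and is a target of the liver X receptors, rose by 1.42 ± 0.23 on the log2 scale (SE, n = 4 per group, adjusted p = 0.0267), or 2.67-fold. Cpsf4l rose by 1.40 ± 0.22, and Gal3st1, which sulphates glycolipids, was detected on 4 high-fat and 0 control arrays and was at least 2.00-fold higher (adjusted p = 0.0275). Ifi27l2b, Them7 and Plscr2, a phospholipid scramblase, rose by 1.13 ± 0.19, 1.00 ± 0.15 and 0.60 ± 0.10. The other probes for Pltp and Them7 changed by 1.29 and 0.71 (adjusted p = 0.0786 and 0.206). Csad, an enzyme of taurine synthesis, fell by 1.21 ± 0.20, and Cyp2j9, a cytochrome P450, fell by 1.11 ± 0.17. Over all genes tested, all 4 high-fat arrays lay on 1 side of all 4 control arrays for 687 (7.27%), where chance gives 2.86%.

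In these females the lists of lipid metabolism leaned upwards without single members passing over all genes. Of the 27 measured fatty acid oxidation and PPAR-alpha target genes, 25 had positive changes (median 0.28) and 0 passed, also 0 when adjusted over the list alone. Camera with its preset correlation placed this list above the other genes (adjusted p = 1.87e-05; adjusted p = 0.633 with an estimated correlation). For lipid droplet genes, 18 of 19 changes were positive (median 0.41), 0 passed over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000546; adjusted p = 0.344 with an estimated correlation). For cholesterol synthesis 15 of 18 were positive (median 0.45), and 0 passed either way (camera adjusted p = 0.00143; adjusted p = 0.677 with an estimated correlation). For fatty acid synthesis 17 of 19 were positive (median 0.17), and 1 passed adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.677 with an estimated correlation). Camera also called oxidative phosphorylation and interferon response upwards, and the growth hormone axis, ER stress and stellate cell lists downwards, with adjusted p = 0.344 to 0.677 with an estimated correlation. Of these, 2 growth hormone axis genes and 1 stellate cell gene fell adjusted over the list alone. With raw intensity as a covariate camera no longer called oxidative phosphorylation (median 0.08 without and 0.0385 with the covariate, adjusted p = 0.0502) or the growth hormone axis (median -0.28 and -0.16, adjusted p = 0.0764). Camera kept its calls of fatty acid oxidation, lipid droplet, ER stress and stellate cell genes whichever array was left out, and each of the others ended without some 1 array. Without control replicate 3 cholesterol synthesis had a median of 0.18 (adjusted p = 0.210) and the growth hormone axis of -0.18 (adjusted p = 0.142). Without high-fat replicate 1 the medians were 0.0823 for fatty acid synthesis, 0.0456 for oxidative phosphorylation, -0.15 for the growth hormone axis and 0.21 for lipid droplet genes (adjusted p = 0.0686, 0.0508, 0.0686 and 0.0420). The interferon response had 0.0368 without high-fat replicate 2 (adjusted p = 0.263), stellate cell genes -0.11 without high-fat replicate 4, ER stress -0.12 without control replicate 1, oxidative phosphorylation 0.0487 without control replicate 2 and lipid droplet genes 0.22 without control replicate 4. Macrophage markers had a median of 0.22 (camera adjusted p = 0.0642) and hepatocyte markers of -0.01 over 20 genes. With raw intensity as a covariate camera called the macrophage markers upwards (median 0.26, adjusted p = 0.0351).

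Of the genes fixed for every offspring-diet comparison, none passed in these females. Cyp4a14, a fatty acid hydroxylase, changed by 0.41 ± 0.29 (SE, adjusted p = 0.608), Fasn, the fatty acid synthase, by 0.48 ± 0.54 (adjusted p = 0.767), and Scd1, a stearoyl-CoA desaturase, by 0.13 ± 0.20 (adjusted p = 0.847). Cd36 was not among the genes tested in either sex. With the log2 mean raw intensity of each array as a covariate, limma called 0 genes; without this covariate 1124 genes had an unadjusted p under 0.05, where 472 would arise by chance. Leaving out 1 array gave between 0 genes and 19, the latter without high-fat replicate 3.

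**Figure D2:**
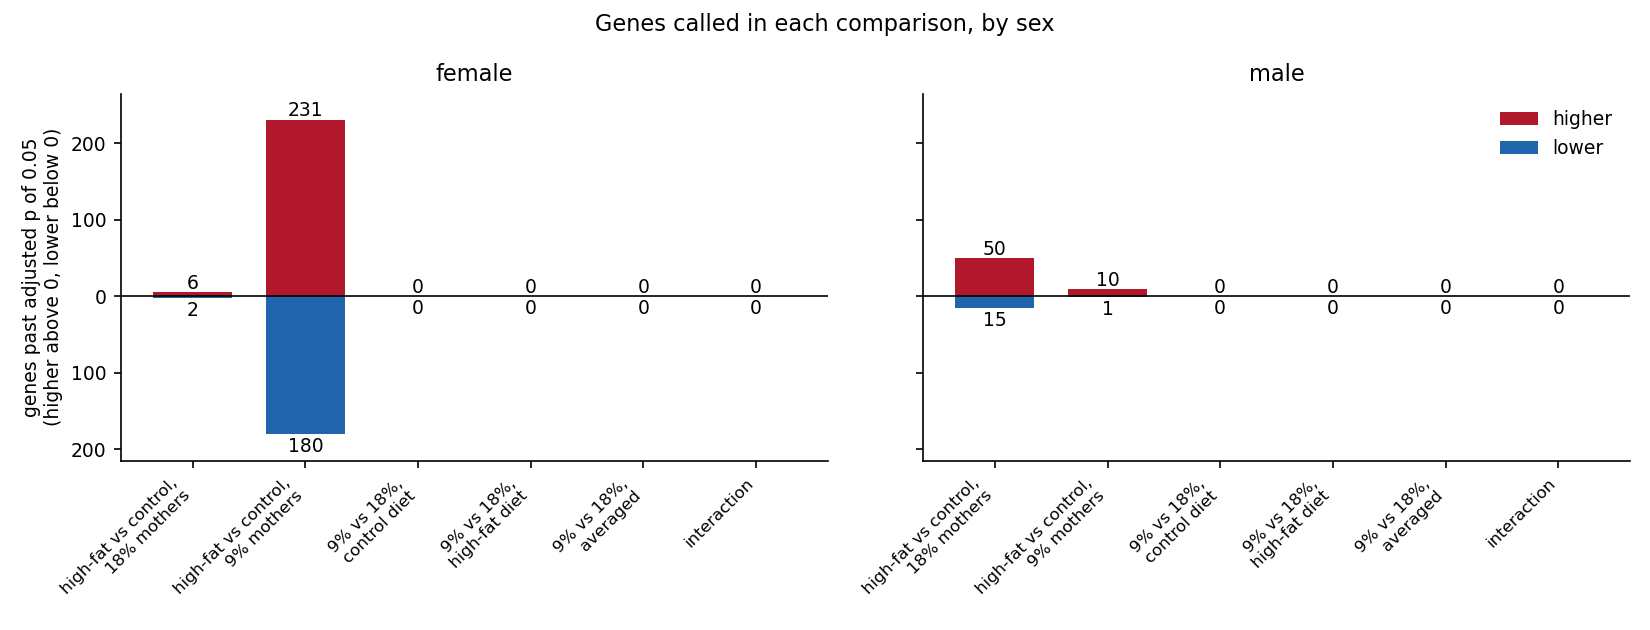
Genes past an adjusted p of 0.05 (y axis, numbers of genes, higher above 0 and lower below 0) in 6 comparisons (x axis), for females on the left and males on the right. High-fat feeding gave 231 higher and 180 lower in females of mothers on 9% and 50 higher and 15 lower in males of mothers on 18%; the comparisons of maternal diets and the interactions gave 0.

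In females of mothers on 9%, the high-fat diet raised 231 genes and lowered 180, of which 57 changed over 2-fold. Gpc1, a heparan sulphate proteoglycan, rose by 2.85 ± 0.54 on the log2 scale (SE, n = 4 per group, adjusted p = 0.0119), and Pltp by 2.37 ± 0.23 (adjusted p = 0.000112), or 5.16-fold. Aqp4, a water channel, was detected on 4 high-fat arrays and 1 control array and was at least 5.92-fold higher (adjusted p = 0.00867). Apoa4, an apolipoprotein of lipid-rich particles, rose by 2.27 ± 0.29, or 4.82-fold. Cidec, a protein that enlarges lipid droplets, and Mogat1, an enzyme of triglyceride synthesis, were detected on 4 high-fat and 0 control arrays and were at least 3.59-fold and 2.69-fold higher (adjusted p = 0.0409 and 0.0258). Serpina1e, a protease inhibitor of plasma, fell by 2.42 ± 0.66, the chemokine Cxcl1 fell by 2.21 ± 0.43, and Insig1, which restrains sterol synthesis, by 1.99 ± 0.51. Irf5, an interferon regulatory factor, Slc22a26, a transporter, and Gss, the glutathione synthetase, fell by 1.25 ± 0.25, 1.22 ± 0.29 and 1.16 ± 0.20. The size of the fall of Insig1 rested on 1 array, as without high-fat replicate 2 it fell by 1.29 (adjusted p = 0.0528). Its other probes changed by -0.48 and -0.43 (adjusted p = 0.361 and 0.459), and those of Gss by -0.82 and -0.49 (adjusted p = 0.00934 and 0.0799).

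**Figure D3:**
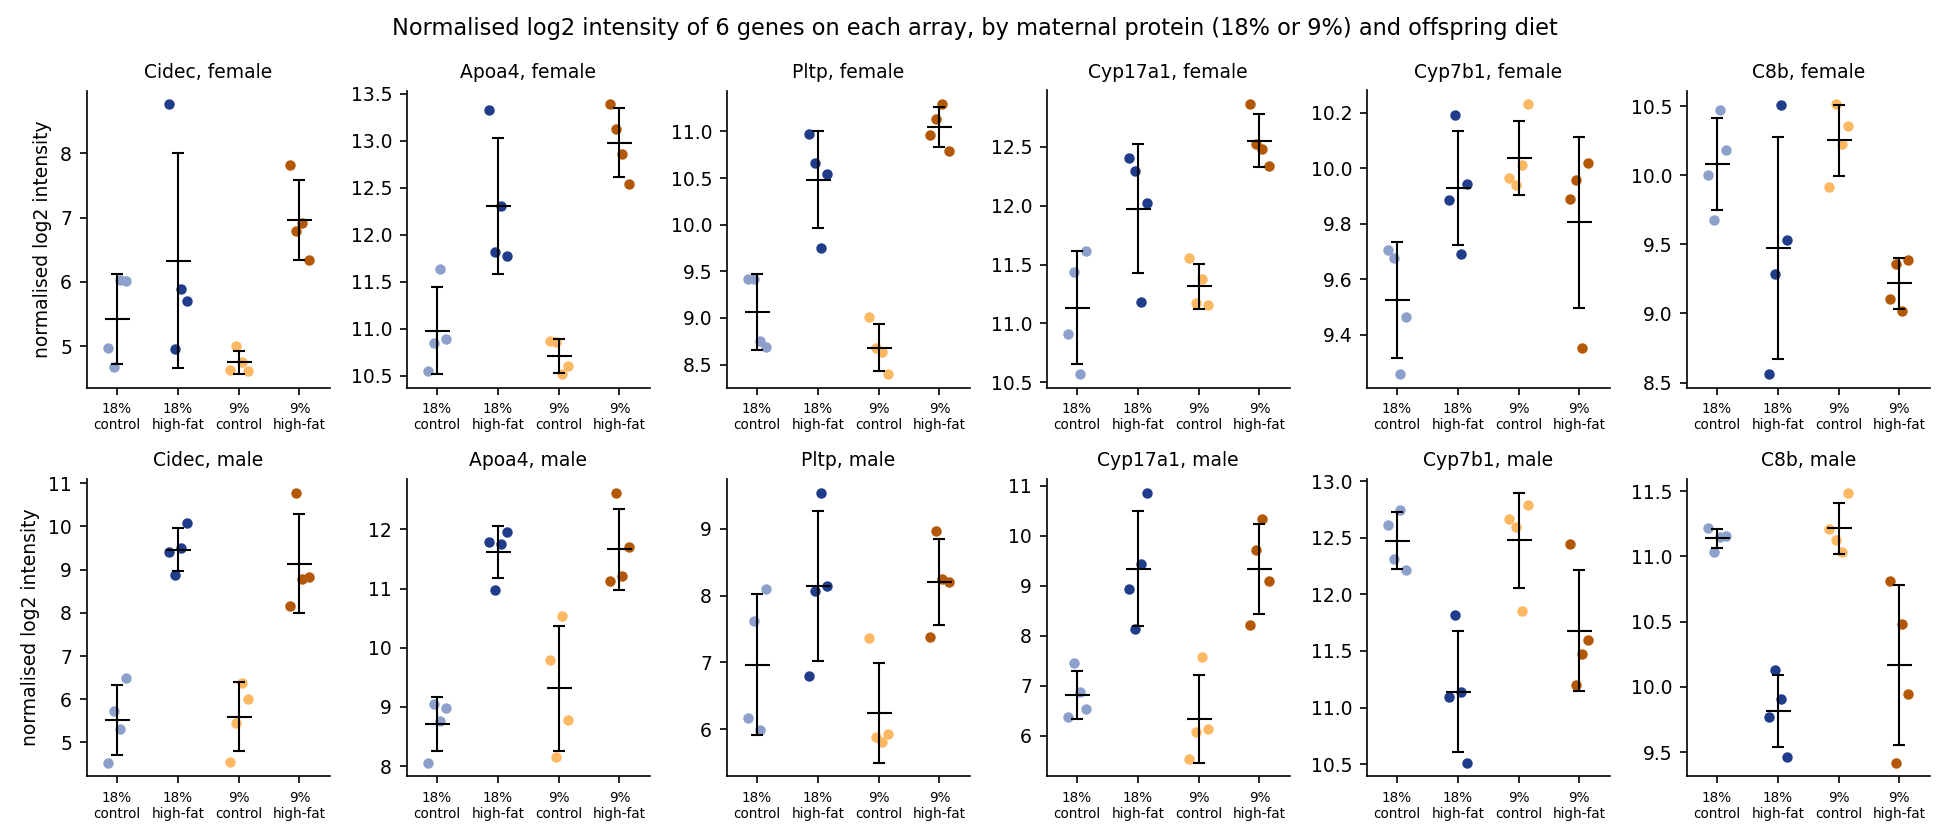
Normalised log2 intensity (y axes, each with its own range) of Cidec, Apoa4, Pltp, Cyp17a1, Cyp7b1 and C8b on each array (points), with mean and SD of the 4 arrays of a group (black), for females above and males below. In males Cidec averaged 5.52 and 9.46 on the control and high-fat diets after maternal 18%.

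Oxidative phosphorylation genes moved most uniformly in these females, with 53 of 54 changes positive (median 0.26). Over all genes 10 rose, and 41 did when adjusted over the list alone. Atp5k and Cox7b, subunits of ATP synthase and of cytochrome c oxidase, rose by 1.19 ± 0.31 (detected on 3 of 4 control arrays) and 0.87 ± 0.18, and Ndufb5, of complex I, by 0.61 ± 0.12. Camera gave an adjusted p = 2.79e-18 for the list (adjusted p = 0.444 with an estimated correlation), and fry, which tests whether the genes of a list move 1 way without comparing them with others, an adjusted p = 0.00882. With raw intensity as a covariate the list's median was 0.17.

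Of 19 lipid droplet genes in the same females 5 rose over all genes, among them Apoa4, Cidec and Mogat1, and 7 adjusted over the list alone (median 0.60; camera adjusted p = 8.16e-05; adjusted p = 0.444 with an estimated correlation; fry adjusted p = 0.0234). Of 19 fatty acid synthesis genes 4 rose and 6 did adjusted over the list alone (camera adjusted p = 0.00285; adjusted p = 0.552 with an estimated correlation). The members that rose act in desaturation, elongation and citrate transport: Fads2 by 1.26 ± 0.25, Fads1 by 0.72 ± 0.10 and Elovl5 by 0.69 ± 0.12, with Slc25a1. Of 18 cholesterol synthesis genes, Dhcr7 and Tm7sf2, both sterol reductases, rose by 1.04 ± 0.19 and 0.71 ± 0.12 and Insig1 fell; adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.00226; adjusted p = 0.552 with an estimated correlation). Of 27 fatty acid oxidation genes 3 rose, Crat, a carnitine acetyltransferase, by 1.17 ± 0.30, Angptl4, a lipase inhibitor, by 1.00 ± 0.23, and Pex11a, of peroxisomes, by 0.92 ± 0.22, and 6 adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.552 with an estimated correlation). The brightest probe carried the call for Crat, whose other probes changed by 0.50 and 0.24 (adjusted p = 0.240 and 0.413). The median of fatty acid synthesis went from 0.41 to 0.13 without control replicate 2 (adjusted p = 0.102), and that of fatty acid oxidation from 0.26 to 0.0990 without control replicate 1 (adjusted p = 0.186).

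Among 31 xenobiotic metabolism genes, 4 rose and 1 fell over all genes, and 9 rose and 3 fell adjusted over the list alone. The aldehyde dehydrogenase Aldh1a7 rose by 1.29 ± 0.19, and the glutathione transferases Gstm2 and Gstt3 by 1.10 ± 0.20 and 0.93 ± 0.17. Camera gave an adjusted p = 0.0346 (adjusted p = 0.552 with an estimated correlation), the same values as for the next list. Among 37 genes of amino acid catabolism and the urea cycle, Bhmt, which remethylates homocysteine, rose by 1.66 ± 0.27, Gpt2, an alanine aminotransferase, by 0.77 ± 0.16, and Csad fell by 0.90 ± 0.20. In all 3 rose and 1 fell, and 5 and 1 adjusted over the list alone. The median of this list went from 0.15 to 0.0980 with raw intensity as a covariate. That of xenobiotic metabolism went from 0.20 to 0.12 without high-fat replicate 1 (adjusted p = 0.0562).

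Falls were found among genes of the endoplasmic reticulum, growth hormone and defence lists. Of 27 ER stress genes, Pdia4, Pdia3 and Xbp1 fell by 0.86 ± 0.17, 0.68 ± 0.09 and 0.54 ± 0.12, 3 in all and also 3 adjusted over the list alone. Camera gave this list an adjusted p = 0.0346 (adjusted p = 0.552 with an estimated correlation). Of 16 genes of the growth hormone axis, Igfals, the partner of circulating IGF, fell by 0.50 ± 0.14 and Jak2, a kinase of cytokine receptors, by 0.40 ± 0.11, and 2 fell adjusted over the list alone; a second Jak2 probe changed by -0.17 (adjusted p = 0.5005). Camera called this list (adjusted p = 0.0485; adjusted p = 0.552 with an estimated correlation). Of 26 interferon response genes, Usp18 and Ddx58 fell by 0.87 ± 0.17 and 0.49 ± 0.13; adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.0346; adjusted p = 0.552 with an estimated correlation). Of 27 acute phase genes, Itih3 fell by 0.82 ± 0.18, with 3 falling adjusted over the list alone (camera adjusted p = 0.0408; adjusted p = 0.552 with an estimated correlation). The immediate early list was lower in 16 of 17 genes with 0 past the threshold either way (camera adjusted p = 0.00226; adjusted p = 0.552 with an estimated correlation). Camera called 0 of these 5 lists with raw intensity as a covariate. The medians without and with it were -0.22 and -0.0660 for ER stress (adjusted p = 0.0514 with it), -0.19 and -0.13 for the growth hormone axis (0.145), -0.17 and -0.0902 for the interferon response (0.216), -0.0860 and -0.0973 for acute phase (0.0731) and -0.61 and -0.42 for immediate early genes (0.0612). Without high-fat replicate 2 they were -0.13 for ER stress, -0.10 for the growth hormone axis and -0.0530 for acute phase (adjusted p = 0.0794, 0.181 and 0.0993). Without control replicate 2 they were -0.0678 for the interferon response, 0.0660 for acute phase and -0.41 for immediate early genes (adjusted p = 0.270, 0.767 and 0.0501). Macrophage, neutrophil and lymphocyte markers had medians of -0.15, -0.34 and -0.10, not called by camera (adjusted p = 0.175, 0.224 and 0.192).

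Cyp4a14, Fasn and Scd1 did not pass in females of mothers on 9%, at 0.16 ± 0.29, 0.41 ± 0.54 and 0.59 ± 0.20 (SE, adjusted p = 0.798, 0.706 and 0.109). Hepatocyte markers had a median change of 0.05 over 20 genes. With raw intensity as a covariate camera also called cell cycle genes upwards (median 0.32, adjusted p = 0.000251). It then called male-biased, stellate cell and endothelial genes downwards (medians -0.17, -0.19 and -0.13, adjusted p = 0.0352, 0.0402 and 0.0402). With raw intensity as a covariate 3 genes were called, while the median size of change of the 411 genes went from 0.58 to 0.47 and the median SE from 0.13 to 0.16; without the 4 dimmest female arrays limma called 0, with 1 high-fat array left against 4 control arrays. With any 1 array left out camera kept its calls of oxidative phosphorylation, lipid droplet and cholesterol synthesis genes, and each of the others ended without some 1 array. Leaving out 1 array gave 83 genes without high-fat replicate 3 and 608 without high-fat replicate 4.

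In males of mothers on 18%, the high-fat diet raised 50 of 10297 genes and unnamed probes and lowered 15, with 35 changing over 2-fold. Cidec, a protein of the lipid droplet surface detected on 3 of 4 control arrays, rose by 3.94 ± 0.51 on the log2 scale (SE, n = 4 per group, adjusted p = 0.00153). Cidea, another such protein, was detected on 4 high-fat arrays and 1 control array and was at least 12.9-fold higher (adjusted p = 0.00533). Apoa4 rose by 2.90 ± 0.43, Cyp17a1, a steroid hydroxylase, by 2.52 ± 0.53, Lgals1, a galectin, by 2.26 ± 0.40, and Osbpl3, a lipid-binding protein, by 2.11 ± 0.41. Cyp1a2, a cytochrome P450 of xenobiotic metabolism, fell by 1.63 ± 0.30, Col27a1 fell by 1.48 ± 0.28, Adgrf1 fell by 1.36 ± 0.26, and Cyp7b1, an oxysterol hydroxylase, by 1.33 ± 0.28. Col27a1 and Adgrf1 were each detected on 2 of 4 high-fat arrays. C8b, a complement component, and the transporter Abca8a had changes of -1.32 ± 0.22 and -1.27 ± 0.25. A second Osbpl3 probe changed by 0.11 (adjusted p = 0.683).

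Of 20 lipid droplet genes measured in these males 7 rose over all genes and 13 adjusted over the list alone, with a median of 0.97. Besides Cidea, Cidec and Apoa4, these were Plin2, Pparg, Fitm1 and Anxa2. Camera gave an adjusted p = 1.02e-10 (adjusted p = 0.0720 with an estimated correlation) and fry an adjusted p = 0.00161. Of 26 fatty acid oxidation genes 4 rose, among them Crat by 1.41 ± 0.30, Cyp4a10, a fatty acid hydroxylase, by 1.32 ± 0.27 and Pex11a by 0.91 ± 0.19, and 11 adjusted over the list alone (camera adjusted p = 1.90e-09; adjusted p = 0.162 with an estimated correlation; fry adjusted p = 0.00685). Camera called the adipocyte markers (adjusted p = 0.0235; adjusted p = 0.184 with an estimated correlation), where Cidea and Cidec were the 2 of 7 that rose; both also stand in the lipid droplet list, and the median of the 7 was 0.07. The adipocyte list had a median of 0.0635 with raw intensity as a covariate (adjusted p = 0.0665). Its adjusted p was 0.0803 without high-fat replicate 3, and its median was 0.00953 without control replicate 3 (adjusted p = 0.0373). A second Cyp4a10 probe changed by 1.62 (adjusted p = 0.105).

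Male-biased liver genes, expressed more in male than in female liver, were lower in 22 of 25 cases in high-fat males of mothers on 18% (median -0.54). Over all genes 4 fell, among them Cyp7b1, C8b and C6, a complement component, which fell by 1.02 ± 0.21, and 13 fell adjusted over the list alone. Camera gave an adjusted p = 1.02e-10 (adjusted p = 0.173 with an estimated correlation) and fry an adjusted p = 0.0173. Among 11 female-biased genes Cyp17a1 alone rose over all genes, and 2 adjusted over the list alone (median 0.53; camera adjusted p = 0.111). Hepatocyte markers had a median of -0.08 over 18 genes.

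Camera also called cell cycle, heat shock and stellate cell genes upwards in these males, with medians of 0.38, 0.32 and 0.26 and adjusted p = 0.555, 0.677 and 0.677 with an estimated correlation, and 0 members of each past the threshold over all genes. Adjusted over the list alone 4 cell cycle genes rose and 1 fell, and 2 heat shock genes rose. Gluconeogenesis genes were called downwards (median -0.30, 0 of 15 past the threshold; adjusted p = 0.555 with an estimated correlation). With raw intensity as a covariate camera no longer called heat shock (median 0.24, adjusted p = 0.176) or gluconeogenesis (median -0.34, adjusted p = 0.0567). It then called immediate early genes upwards (median 0.84, adjusted p = 0.0164). Cyp4a14 changed by 2.99 ± 0.69 (SE, adjusted p = 0.0666), Fasn by 0.13 ± 0.27 (adjusted p = 0.840) and Scd1 by 0.20 ± 0.13 (adjusted p = 0.480). Of the list calls in these males, those of lipid droplet, fatty acid oxidation and male-biased genes were kept whichever array was left out, and each of the others ended without some 1 array. Without high-fat replicate 4 cell cycle genes had a median of 0.24 and stellate cell genes of 0.14 (adjusted p = 0.0651 and 0.128). Gluconeogenesis had -0.17 without control replicate 2 (adjusted p = 0.322), and heat shock 0.24 without high-fat replicate 3 (adjusted p = 0.451). With raw intensity as a covariate 25 genes were called, and with array weights 114. Leaving out 1 array gave 9 genes without high-fat replicate 4 and 102 without high-fat replicate 3.

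In males of mothers on 9%, the high-fat diet raised 10 genes and lowered 1. Cidec, detected on 3 of 4 control arrays, rose by 3.54 ± 0.51 on the log2 scale (SE, n = 4 per group, adjusted p = 0.00666). Cidea was detected on 4 high-fat and 0 control arrays and was at least 8.38-fold higher (adjusted p = 0.0443), or at least 4.56-fold without high-fat replicate 2 (adjusted p = 0.00807). Cyp17a1 rose by 3.00 ± 0.53, Apoa4 by 2.35 ± 0.43, Gpx6, named as a glutathione peroxidase and detected on 3 of 4 control arrays, by 1.88 ± 0.30, and Fitm1, a protein of lipid droplet formation, by 1.68 ± 0.24. Itih3, a matrix-binding plasma protein, was the gene that fell, by 0.68 ± 0.12. Gstt3 rose by 1.15 ± 0.18. Of these, Cidec, Cidea, Cyp17a1, Apoa4, Fitm1 and Gstt3 also passed in males of mothers on 18%, where 8 of the 11 were shared and 0.0694 would be if the lists were independent.

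Of 20 lipid droplet genes in these males 4 rose over all genes and 8 adjusted over the list alone (median 0.61; camera adjusted p = 4.89e-11; adjusted p = 0.0608 with an estimated correlation; fry adjusted p = 0.00853). For 26 fatty acid oxidation genes 0 passed over all genes and 3 adjusted over the list alone, with 23 positive (median 0.38; camera adjusted p = 4.97e-07; adjusted p = 0.181 with an estimated correlation). Cholesterol synthesis was positive in 18 of 19 genes (median 0.40) and fatty acid synthesis in 14 of 18 (median 0.37), each with 0 past the threshold over all genes and 1 adjusted over the list alone. Camera gave these an adjusted p = 8.12e-05 and 0.000648 (adjusted p = 0.543 and 0.422 with an estimated correlation). Oxidative phosphorylation was positive in 45 of 47 genes (median 0.10) with 0 passing either way (camera adjusted p = 4.97e-07; adjusted p = 0.403 with an estimated correlation). The median of fatty acid synthesis was 0.12 without control replicate 2 (adjusted p = 0.137). Lists that kept their call at lower medians were cholesterol synthesis at 0.24 without control replicate 3 and 0.25 without high-fat replicate 2, and oxidative phosphorylation at 0.0515 without control replicate 1.

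Of 25 male-biased genes 23 were lower in high-fat males of mothers on 9% (median -0.32), 0 over all genes and 2 adjusted over the list alone (camera adjusted p = 4.14e-06; adjusted p = 0.344 with an estimated correlation). Of 11 female-biased genes Cyp17a1 rose, 2 did adjusted over the list alone, and the median was 0.55 (camera adjusted p = 0.000352; adjusted p = 0.248 with an estimated correlation). The adipocyte markers were again called through Cidea and Cidec, 2 of 7 (camera adjusted p = 0.00120; adjusted p = 0.0894 with an estimated correlation). Camera also called xenobiotic metabolism, amino acid catabolism and red blood cell genes upwards and lymphocyte markers downwards, with adjusted p = 0.181 to 0.632 with an estimated correlation. With the replicate number as a block 10 of the 12 list calls in these males were kept. With raw intensity as a covariate xenobiotic metabolism was no longer called (median 0.12, adjusted p = 0.0641), and the interferon response was called downwards (median -0.19, adjusted p = 0.0305). The calls of xenobiotic metabolism, amino acid catabolism, fatty acid synthesis, red blood cell and lymphocyte genes each ended without some 1 array, and the others were kept. Xenobiotic metabolism had a median of 0.0480 without high-fat replicate 2 (0.14 with all arrays), amino acid catabolism of 0.0632 without high-fat replicate 3 (0.14) and lymphocyte markers of -0.0580 without control replicate 1 (-0.16), with adjusted p = 0.180, 0.353 and 0.668. Xenobiotic metabolism also had 0.0907 and 0.0808 without control replicates 2 and 4 and 0.0827 without high-fat replicate 3 (adjusted p = 0.0673, 0.0682 and 0.0439). Without high-fat replicate 1 the medians of female-biased and male-biased genes were 0.83 and -0.54, and without control replicate 2 that of the adipocyte markers was 0.0719 (0.15 with all arrays). Cyp4a14, Fasn and Scd1 changed by 1.13 ± 0.69, 0.17 ± 0.27 and 0.29 ± 0.13 (SE, adjusted p = 0.621, 0.881 and 0.471). With only the arrays of the groups compared 1 gene was called, and leaving out 1 array gave 6 to 22 genes, the latter without the control replicate 3 of mothers on 9%.

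**Figure D4:**
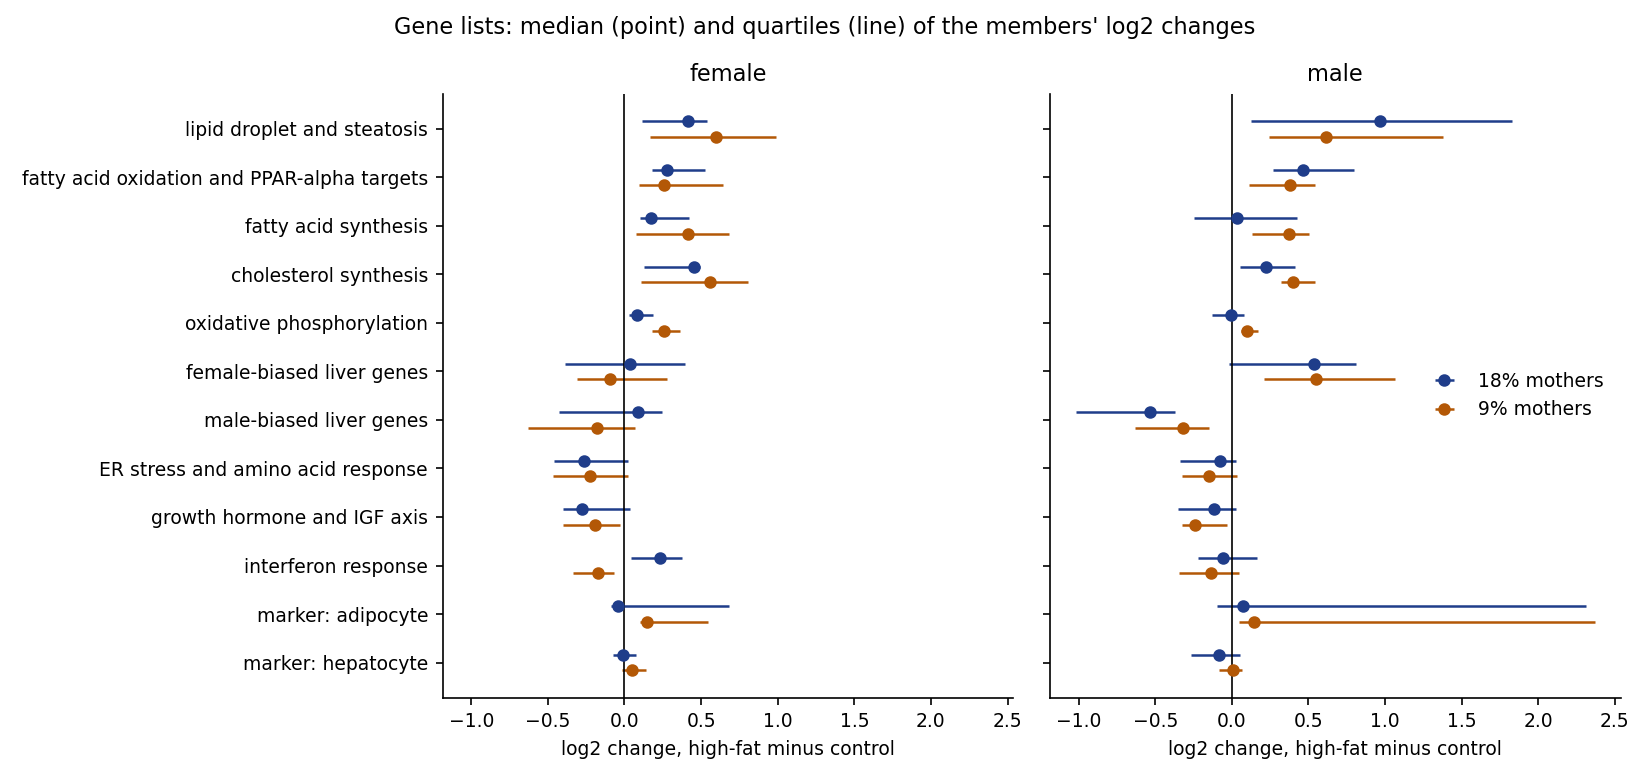
Median (point) and quartiles (line) of the log2 changes, high-fat minus control (x axis), of the members of 12 gene lists (y axis), for females on the left and males on the right and for offspring of mothers on 18% and on 9%. In males the lipid droplet list has medians of 0.97 and 0.61 and the male-biased list of -0.54 and -0.32, while the hepatocyte list lies at -0.08 and 0.01.

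The effect of the maternal diet was then asked within each offspring diet. In females on the control diet 0 genes passed in limma (593 at an unadjusted p under 0.05, 472 by chance). The smallest p-values were those of Bpnt1, a nucleotide phosphatase, at 0.91 ± 0.18 on the log2 scale (9% minus 18%, SE, n = 4 per group), Esm1, an endothelial proteoglycan detected on 2 of 4 arrays after 9%, at -2.81 ± 0.56, and Smtn, a smooth muscle protein, at -0.71 ± 0.14, each with adjusted p = 0.367. A second Bpnt1 probe had the opposite sign, at -0.09. Bile duct markers were lower in 7 of 7 genes (median -0.45), with 2 falling adjusted over the list alone (camera adjusted p = 0.000659; adjusted p = 0.0836 with an estimated correlation; fry adjusted p = 0.0300). Stellate cell and matrix genes were lower in 20 of 21 (median -0.29; camera adjusted p = 2.29e-06; adjusted p = 0.473 with an estimated correlation), and male-biased genes higher in 18 of 22 (median 0.21; camera adjusted p = 0.000846; adjusted p = 0.473 with an estimated correlation), with 0 members of either past the threshold adjusted over the list alone. The other camera calls were amino acid catabolism and oxidative phosphorylation downwards and acute phase, interferon response and heat shock upwards, with adjusted p = 0.473 to 0.765 with an estimated correlation. Each of these 5 calls ended without some 1 array, while those of bile duct, stellate cell and male-biased genes were kept. Without control replicate 2 after 9% acute phase genes had a median of -0.0445 (0.0512 with all arrays) and the interferon response of 0.0689 (0.12), with adjusted p = 0.587 and 0.386. Oxidative phosphorylation had -0.0202 without control replicate 4 after 18% (-0.0540 with all arrays, adjusted p = 0.880), and bile duct markers -0.28 without control replicate 3 after 18%. Among the genes fixed for maternal comparisons, Nr1h3, a liver X receptor, changed by 0.20 ± 0.09, Ppara by -0.21 ± 0.14, Pck1, of gluconeogenesis, by -0.33 ± 0.26 and Cyp7a1, of bile acid synthesis, by 0.49 ± 0.49, with adjusted p = 0.772 to 0.922.

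In high-fat females 0 genes passed between maternal diets in limma, with 898 at an unadjusted p under 0.05 (472 by chance). Sgk1, a kinase induced by glucocorticoids, Usp18, of the interferon response, and Per1, a clock gene, had the smallest p-values, at -0.61 ± 0.12, -0.85 ± 0.17 and -0.86 ± 0.18 on the log2 scale (9% minus 18%, SE, n = 4 per group), each with adjusted p = 0.354. Oxidative phosphorylation genes were higher in 52 of 54 (median 0.12), with 0 adjusted over the list alone (camera adjusted p = 1.25e-07; adjusted p = 0.738 with an estimated correlation). Interferon response genes were lower in 21 of 26 (median -0.30), with 1 falling adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.738 with an estimated correlation). Clock genes were lower in 13 of 18 (median -0.83), and adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.0297; adjusted p = 0.738 with an estimated correlation). Immediate early genes were lower in 16 of 17 (median -0.52; camera adjusted p = 7.39e-05; adjusted p = 0.738 with an estimated correlation), and macrophage, lymphocyte and stellate cell markers were called downwards with adjusted p = 0.781 to 0.794 with an estimated correlation. The arrays of these groups also differed in mean raw intensity, 343 ± 48.9 units after maternal 9% and 385 ± 44.5 after 18% (SD, n = 4). With it as a covariate camera no longer called the clock (median -0.53, adjusted p = 0.101) or lymphocyte lists (median -0.16, adjusted p = 0.0793), and the median of oxidative phosphorylation was 0.0791. Camera then also called heat shock genes upwards (median 0.22, adjusted p = 0.00697) and endothelial genes downwards (median -0.0877, adjusted p = 0.0363). Camera kept its calls of oxidative phosphorylation and immediate early genes whichever array was left out; the clock call ended without high-fat replicate 1 after 9% (median -0.48, adjusted p = 0.155) and the interferon call without high-fat replicate 2 after 18% (median -0.13, adjusted p = 0.0895). Without that array macrophage, lymphocyte and stellate cell markers had medians of -0.0910, -0.0930 and -0.0573 (-0.16, -0.19 and -0.15 with all arrays), with adjusted p = 0.292, 0.296 and 0.256. Each of these 3 calls also ended without other arrays, and stellate cell genes had -0.0879 without high-fat replicate 1 after 18% and -0.0980 without high-fat replicate 4 after 9% (adjusted p = 0.315 and 0.331). Immediate early genes had a median of -0.33 without high-fat replicate 4 after 18%, and macrophage markers of -0.10 without high-fat replicate 3 after 9%. Nr1h3, Ppara, Pck1 and Cyp7a1 changed by 0.12 ± 0.09, -0.06 ± 0.14, -0.48 ± 0.26 and -1.40 ± 0.49, with adjusted p = 0.430 to 0.913.

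In males on the control diet 0 genes passed between maternal diets in limma, with 379 at an unadjusted p under 0.05 (515 by chance). P2ry6, a nucleotide receptor, Pklr, the liver pyruvate kinase, and Blzf1, a Golgi protein, had the smallest p-values, with adjusted p = 0.862, 1.000 and 1.000. P2ry6 and Pklr changed by 0.79 ± 0.15 and -1.40 ± 0.33 on the log2 scale (9% minus 18%, SE, n = 4 per group). Blzf1 was detected on 4 arrays after 9% and 1 after 18% and was at least 1.23-fold higher after 9%. Fatty acid synthesis genes were lower in 15 of 18 (median -0.43; camera adjusted p = 2.41e-05; adjusted p = 0.560 with an estimated correlation), and cholesterol synthesis genes in 16 of 19 (median -0.24; camera adjusted p = 0.00126; adjusted p = 0.634 with an estimated correlation). Macrophage markers were higher in 20 of 20 (median 0.32; camera adjusted p = 1.52e-05; adjusted p = 0.560 with an estimated correlation) and lymphocyte markers in 12 of 12 (median 0.24; camera adjusted p = 5.26e-05; adjusted p = 0.560 with an estimated correlation). Of these 4 lists, 1 lymphocyte gene passed adjusted over the list alone. Camera further called stellate cell and matrix (median 0.26), immediate early (0.65), cell cycle (0.22) and fatty acid oxidation genes (0.0949) upwards, and the clock (-0.41), gluconeogenesis (-0.17), red blood cell (-0.13) and amino acid catabolism genes (-0.0681) downwards. These 8 had adjusted p = 0.159 to 0.634 with an estimated correlation. With raw intensity as a covariate camera no longer called fatty acid oxidation (median 0.0832, adjusted p = 0.0697) or the clock (median -0.38, adjusted p = 0.0776). Only the lymphocyte, stellate cell and red blood cell calls were kept whichever array was left out. Immediate early genes had a median of -0.0152 without control replicate 1 after 18% (adjusted p = 0.546), and cholesterol synthesis genes of -0.0147 without control replicate 4 after 18% (adjusted p = 0.801). Macrophage markers had a median of 0.13 without control replicate 1 after 9% (adjusted p = 0.437), and fatty acid synthesis genes of -0.20 without control replicate 2 after 9% (adjusted p = 0.0552). Without control replicate 3 after 9% the medians were 0.0269 for fatty acid oxidation, 0.13 for cell cycle, -0.15 for cholesterol synthesis and 0.16 for stellate cell genes (adjusted p = 0.803, 0.394, 0.114 and 0.0323). Gluconeogenesis had -0.0439 without control replicate 2 after 18%, the clock -0.15 without control replicate 4 after 9% and -0.19 without control replicate 3 after 18%, and fatty acid oxidation 0.0414 without control replicate 2 after 9% (adjusted p = 0.439, 0.576, 0.385 and 0.202). Lymphocyte markers kept their call at 0.0920 without control replicate 1 after 9%. Nr1h3, Ppara, Pck1 and Cyp7a1 changed by 0.04 ± 0.15, 0.03 ± 0.26, -0.30 ± 0.27 and -0.85 ± 0.77, each with adjusted p = 1.000; a second Nr1h3 probe had -0.16. On the deposited normalised values 3 genes passed.

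In high-fat males 0 genes passed between maternal diets in limma, with 713 at an unadjusted p under 0.05 (515 by chance). Stoml2, a mitochondrial membrane protein, and Dner, a Notch ligand, were detected on 4 arrays after maternal 18% and 0 after 9%, and were at least 1.17-fold and 1.51-fold lower after 9% (adjusted p = 0.433 and 0.671), while Plekhj1, detected on 2 of 4 arrays after 18%, changed by 0.57 ± 0.13 on the log2 scale (SE, n = 4 per group, adjusted p = 0.671). Oxidative phosphorylation genes were higher in 41 of 47 (median 0.15), with 0 adjusted over the list alone (camera adjusted p = 7.02e-09; adjusted p = 0.951 with an estimated correlation). Nr1h3, Ppara, Pck1 and Cyp7a1 changed by 0.09 ± 0.15, 0.10 ± 0.26, -0.05 ± 0.27 and -0.47 ± 0.77, with adjusted p = 0.899 to 0.980.

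Averaged over offspring diets, 0 genes passed for the maternal diet in females or males in limma, with 982 and 344 at an unadjusted p under 0.05 (472 and 515 by chance). In females stellate cell and immediate early genes were called lower by camera (medians -0.22 and -0.58) and heat shock genes higher (0.12), with adjusted p = 0.609, 0.609 and 0.670 with an estimated correlation. In males macrophage, lymphocyte and oxidative phosphorylation genes were called higher (medians 0.26, 0.14 and 0.06) and fatty acid synthesis, cholesterol synthesis and red blood cell genes lower (medians -0.22, -0.16 and -0.08), with adjusted p = 0.367 to 0.818 with an estimated correlation. Of these the heat shock, male cholesterol synthesis and male red blood cell calls ended without some 1 array, with medians of 0.0751 without control replicate 2 after 18%, -0.0958 without control replicate 4 after 18% and -0.0531 without high-fat replicate 4 after 9% (adjusted p = 0.0702, 0.382 and 0.0710). Male macrophage markers kept their call at 0.11 without control replicate 1 after 9%, and fatty acid synthesis and oxidative phosphorylation at -0.14 and 0.0381 without control replicate 2 after 9%. On simulated changes of 1 log2 unit in 67 genes, the same test recovered 66 in females and 66 in males, and of changes of 0.5 it recovered 55 and 45. The simulation held 200 changed genes that varied independently. With fewer changed genes the adjusted threshold is harder to pass, so these numbers do not give the chance of finding a few real maternal changes. Leaving out 1 female array gave up to 8 genes, without control replicate 2 of mothers on 18%.

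Whether the high-fat effect differed between maternal diets was tested as an interaction, and 0 genes passed in either sex. In females 500 genes had an unadjusted p under 0.05 in limma (472 by chance), and Usp18, Cyp2j9 and Zfp612 had the smallest p-values, at -1.08 ± 0.24, 0.99 ± 0.24 and -0.71 ± 0.18 on the log2 scale (SE, each with adjusted p = 0.875). The numbers of 411 and 8 genes called in females after maternal 9% and 18% were therefore not shown to differ at any single gene. In males 699 had an unadjusted p under 0.05 (515 by chance), and Stoml2, Dner and Myom2, a sarcomere protein, were nearest to the threshold (adjusted p = 0.0544, 0.0927 and 0.124). No size is given for these, since Stoml2 was detected on 4 of 4 arrays in high-fat males after 18% and on 0 in the other groups, and Dner and Myom2 on 0 of 4 arrays in both control males after 18% and high-fat males after 9%. On the deposited normalised values 3 genes passed in males.

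Whether the sexes differed was tested over the 6941 genes measured in both. In the high-fat effect averaged over maternal diets 3 genes differed, each with a higher change in males. Rps19, a ribosomal protein, changed by -0.03 ± 0.06 in females and 1.01 ± 0.16 in males, where it was detected on 6 of 8 control arrays (difference 1.04 ± 0.18, SE, 8 arrays per diet and sex, adjusted p = 0.0107). Ubr1, a ubiquitin ligase, changed by -0.33 ± 0.07 and 0.50 ± 0.13 (difference 0.83 ± 0.14, adjusted p = 0.0107), and Tm4sf4, a membrane protein, by -0.40 ± 0.10 and 0.53 ± 0.14 (difference 0.93 ± 0.18, adjusted p = 0.0323). All 3 were measured by different probes in the sexes, so the probe and the sex cannot be told apart for them. With raw intensity as a covariate 0 passed in limma, and 739 had an unadjusted p under 0.05 without it (347 by chance). The maternal effect differed between the sexes at 0 genes in limma (546 at an unadjusted p under 0.05); Pdgfb, a growth factor detected on 7 of 8 female and 6 of 8 male high-fat arrays, Ube2n, a ubiquitin-conjugating enzyme, and Itpkc, an inositol phosphate kinase, were nearest, with differences of 0.76 ± 0.16, -0.41 ± 0.09 and 0.76 ± 0.19 (adjusted p = 0.388, 0.388 and 0.417).

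Genes raised by the high-fat diet were shared between the sexes in 3 of the 4 pairs of groups. Of genes raised in females of mothers on 9% and in males of mothers on 18%, 17 were shared where 1.03 would be by independence, among them Apoa4, Cidec, Crat, Cyp17a1, Gpc1, Gstt3, Lgals1 and Pex11a. Abca8a, C8b and Pdia5 were the 3 shared among those that fell (0.249 by independence). Females of mothers on 9% and males of mothers on 9% shared 6 raised genes (0.211 by independence), Apoa4, Cidec, Cyp17a1, Fitm1, Gstt3 and Lamb3, and 1 that fell, Itih3. Females of mothers on 18%, with 6 raised genes measured in both sexes, shared 2 with males of mothers on 18%, Gal3st1 and Plscr2 (0.0337 by independence), and 0 with the 8 raised in males of mothers on 9% (0.00692 by independence). They shared 0 of their 2 falling genes with either. Of the 316 genes called in females of mothers on 9% that were measured in males, 285 (90.2%) had the same sign in the male high-fat effect averaged over maternal diets.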

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

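Among the tests below, that of raw intensity as the whole cause of the female changes was chosen only after the result was seen, and the covariates and the clock gene sets were added after the data were seen.

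The high-fat diet called 411 genes in females of mothers on 9% and 8 in females of mothers on 18%. Of the 411 genes, 395 (96.1%) had the same sign after 18%, with a median change of 0.272 in the direction seen after 9%. Of the 8 genes, 5 were among the 411, where 0.348 would be if the lists were independent. This does not separate diet from intensity, as high-fat arrays were dimmer on average after both maternal diets. The median change of the 411 genes after 9% was 0.577 without and 0.468 with intensity as a covariate. The calls ended at 3 as the median SE went from 0.134 to 0.164. These genes were chosen by their change on the same arrays, so this cannot decide whether raw intensity was the whole cause. Averaged over maternal diets, limma called 212 genes and unnamed probes for the high-fat diet in males, and 170 of these were named and measured in females. Over these 170, signed by their male direction, the female high-fat effect was 0.33 after 18% and 0.54 after 9%, an interaction of 0.21 ± 0.13 (SE, exact permutation p = 0.136, two-sided). With the covariate it was 0.143 ± 0.121, so a stronger response after maternal 9% and a difference in array intensity may each account for the gap and cannot be told apart here. Regrouping the maternal labels within offspring diets gave a gap of 403 calls or more in 9 of 100 draws, the real grouping among them. Other draws gave up to 910, so chance cannot be excluded for the gap, and draws that high point to a structure of the samples.

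The clock list had an interaction of the diets with a median of -0.70 in females (camera adjusted p = 0.0417; adjusted p = 0.626 with an estimated correlation), and the call ended without any 1 of 8 arrays, so the groups are not shown to differ. Within groups, the mean of 3 genes of the early arm and that of 9 genes of the late arm ran against each other over 16 female arrays (Pearson r = -0.959, permutation p = 0.00017; Spearman rho = -0.953, p = 1e-05, the smallest that 100000 permutations give; adjusted over 2 sexes 0.00017 and 2e-05), and r was -0.926 without the 2 farthest arrays. That is consistent with animals of a group having been sampled at different times of day, which the labels do not give. A single array as the cause is argued against, since the interaction of the phase, 2.50 ± 1.52 (SE), stayed at 1.71 or more without any 1 array. An effect of the diets on the clock stays open, with an exact permutation p = 0.152 (two-sided) for the interaction; between maternal diets the phase difference was 2.61 in high-fat females (exact p = 0.0286, the smallest that 4 against 4 arrays give; adjusted p = 0.114 over 4 comparisons) and 0.11 in control females (exact p = 0.943).

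Whether chance groupings of the arrays give as many genes was asked for each comparison. For the high-fat diet the real split gave the most genes in each comparison, as 1 of 35 splits. That is the smallest share 35 splits can give and was not adjusted over the comparisons, so chance is argued against but not excluded. The real splits gave 8 in females after 18% (highest other 3), 411 after 9% (47), 65 in males after 18% (1) and 11 after 9% (0). For the maternal diet the real splits gave 0 genes, which any of the 35 splits must reach, so the splits test nothing there; the highest others were 16 and 100 in control and high-fat females and 4 and 9 in males. The split with 100 set the 4 dimmest high-fat female arrays against the 4 brightest, a structure of the samples. The same holds for the 0 genes of the maternal average and of the interaction, where the highest of 100 regroupings gave 6 and 33 in females and 91 and 1 in males. The 91 also points to a structure of the samples. For the sex difference in the high-fat effect 1 of 100 regroupings, the real one, gave 3 genes (highest other 1). These regroupings remove the high-fat effect from both sexes. They therefore do not test whether equal effects in the sexes would give as many. For the maternal effect the real count was 0, which tests nothing (highest other 1).

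For lists called by camera, as many were called in 13 of 35 splits in females after 18% (9 real, 14 highest other), in 2 after 9% (12 and 12), in 5 in males after 18% (8 and 12) and in 8 after 9% (12 and 17). Between maternal diets the splits were 22 and 18 of 35 in control and high-fat females (8 real and 14 highest other, 7 and 12) and 7 and 33 in males (12 and 14, 1 and 10). Chance can be excluded for none of these numbers of lists.

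The high-fat effect differed between the sexes by 1.04 for Rps19, 0.93 for Tm4sf4 and 0.83 for Ubr1 (male minus female). The interaction of the diets was called by camera for 8 lists in females, with medians of 0.10 for xenobiotic metabolism, -0.24 for male-biased genes, -0.70 for the clock, 0.16 for amino acid catabolism, 0.18 for oxidative phosphorylation, -0.37 for the interferon response, -0.36 for macrophage markers and 0.30 for bile duct markers (adjusted p = 0.307 for the last and 0.626 for the others with an estimated correlation). Without high-fat replicate 3 after 18% the medians of xenobiotic metabolism and male-biased genes were 0.0505 and -0.16, without high-fat replicate 1 after 9% that of the clock was -0.44, and without control replicate 2 after 9% that of macrophage markers was -0.16 (adjusted p = 0.370, 0.227, 0.103 and 0.340). Macrophage markers also had -0.23 without control replicate 2 after 18% and high-fat replicate 2 after 18% (adjusted p = 0.111 and 0.0494). Amino acid catabolism had 0.0997 without control replicate 3 after 18%, and the interferon response kept its call at -0.21 without high-fat replicate 2 after 18%. In males 4 lists were called, gluconeogenesis at 0.28, male-biased genes at 0.27, oxidative phosphorylation at 0.16 and stellate cell markers at -0.37 (adjusted p = 0.797 with an estimated correlation). Without high-fat replicate 1 after 9% the median of male-biased genes was 0.0744 (adjusted p = 0.487), and without control replicate 1 after 9% that of oxidative phosphorylation was 0.0946 (adjusted p = 0.00897). Of the 12 interaction calls in both sexes 7 ended without some 1 array.

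Single arrays lay far from the other 3 of their group in 25 of 394 sets of values; chance flags about 1 in 20 groups, or 19.7 of these. Female high-fat replicate 4 of mothers on 9% stood at 1.64 on the first principal component (others 21.4 to 23.6), and at 14.15 for Elovl5, 7.50 for Crat, 12.6 for Cyp7a1 (others 10.73 to 10.78) and 0.147 for the macrophage score. Replicate 3 of that group stood at 9.59 for Dhcr7, 10.83 for Pex11a, 7.49 for Atp5k and 10.59 for Cox7b, and replicate 2 at 6.51 for Insig1 (others 9.13 to 9.57), 6.11 for Gss and 6.94 for Cyp2j9. In the other female groups these were Gal3st1 at 6.78 (high-fat replicate 1 after 18%), Sgk1 at 11.33 (high-fat replicate 3 after 18%), Plscr2 at 8.57 (control replicate 1 after 18%), Gpt2 at 10.92 and Ddx58 at 7.80 (control replicates 4 and 3 after 9%), and the growth hormone axis score at 0.0879 (control replicate 4 after 18%). In males they were Cidea at 10.5 (high-fat replicate 2 after 9%, others 6.81 to 7.11), Col27a1 at 7.12 and Blzf1 at 5.11 (control replicates 2 and 3 after 18%), Nr1h3 at 10.44 and the lymphocyte score at 0.489 (control replicate 1 after 9%), the heat shock score at 0.0127 (control replicate 3 after 18%) and the immediate early score at -2.18 (control replicate 1 after 18%, others 0.13 to 0.37).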

How the results depend on the processing

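The covariates for raw intensity and clock phase, the omission of the 4 dimmest female arrays, the list calls and bounds with 1 array left out and the permutation of replicate numbers were tests chosen only after the results were seen. None of the 72 results for named genes past the threshold changed sign under any setting, and 26 passed whichever array was left out. The rule named genes with large changes, many with groups that did not overlap, so the kept signs say little about stability. Of 49 not past the threshold, signs changed in 20 values. The number of arrays and the signal over background limit what can be detected, and where no cause is named below, the cause was not tested.

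Without background correction, and also on the deposited normalised values, limma called 17 genes for the high-fat diet in males after 9%, 3 for the maternal diet in control males and 3 for the male interaction. Without a filter on dim probes there were 219 for the high-fat diet in females after 9%, 1 for the male interaction and 6 for the sex difference in the high-fat effect. With a detection p under 0.01 required on all 16 arrays, which changes both the threshold and the number of arrays, the high-fat diet in males called 36 after 18% and 7 after 9%. With all probes tested there were 26 in males after 9% and 1 for the maternal average in females. With only the compared groups, and so fewer arrays, there were 3 and 213 in females after 18% and 9% and 1 in males after 9%. Array weights gave 114 and 26 in males after 18% and 9%, 1 for the male interaction and 5 for the sex difference, and moved Ppara in control males to -0.12.

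With raw intensity as a covariate the high-fat diet called 0 and 3 genes in females after 18% and 9%, 25 and 7 in males, 2 for the male interaction and 0 for the sex difference; 12 of 72 named results kept their call. Without the 4 dimmest female arrays it called 2 and 0 in females and 0 for the sex difference, and Nr1h3 and Ppara moved to -0.0149 and 0.0519 between maternal diets in high-fat females. This left 1 high-fat array after 9%, set against 4 controls or 3 high-fat arrays after 18% and assumed to vary like the other groups, so these values say little about stability. With clock phase as a covariate males after 9% had 23 genes, and Pck1 between maternal diets in high-fat males was 0.00259.

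With the replicate number as a block the sex difference had 7 genes, and the block moved no other count by over 1.5 times. It kept 66 of 72 named results past the threshold and 87 of 90 camera calls. The lost camera calls lay in the high-fat diet in males after 9%, with 10 of 12 kept, and in the female interaction, with 7 of 8 kept. Same-numbered arrays were not treated as pairs: correlations of their deviations ran from -0.201 to 0.320 in females and -0.157 to 0.490 in males, with 10 of 24 over 0.1 in each. In females 7 of 16 arrays and in males 10 of 16 correlated best with their own number, where chance gives 4 (exact permutation p = 0.129 and 0.0119, one-sided, adjusted p = 0.129 and 0.0237). The mean correlation of same-numbered arrays was 0.0737 in females and 0.0856 in males (exact permutation, adjusted p = 0.0502 in both). The male numbers thus hint at a shared structure that the labels do not give, by the first of these tests alone.

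Leaving out 1 array gave 0 to 19 genes for the high-fat diet in females after 18%: 0 without control replicates 1 or 4 or high-fat replicates 1 or 4, 1 without high-fat replicate 2 and 19 without high-fat replicate 3. After 9% it gave 83 to 608: 220, 255, 159 and 137 without control replicates 1 to 4, and 227, 122 and 83 without high-fat replicates 1 to 3. In males after 18% it gave 9 to 102: 14, 11 and 20 without control replicates 2 to 4, and 14, 102 and 9 without high-fat replicates 1, 3 and 4. In males after 9% it gave 6 to 22: 7, 22 and 7 without control replicates 2 to 4, 7 without high-fat replicate 2, and 7, 6 and 7 without control replicates 2 and 4 and high-fat replicate 3 after 18%. The maternal diet gave 0 to 2 in control females (2 without control replicate 2 after 18%), 0 to 4 in high-fat females (4 without high-fat replicate 4 after 9%) and 0 to 8 on average: 8 and 1 without control replicates 2 and 1 after 18%, 1 without high-fat replicate 4 after 18%, and 1 and 5 without control replicate 3 and high-fat replicate 4 after 9%. The male interaction gave 0 to 2 (2 without high-fat replicate 4 after 18%). The sex difference gave 2 to 20: after 18%, 5, 18 and 20 without male high-fat replicates 1 to 3 and 5 without male control replicates 1 or 4; after 9%, 6 and 5 without male control replicates 1 and 3, 5 and 6 without male high-fat replicates 1 and 4, 6 without female control replicate 3 and 5 without female high-fat replicate 1.

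Of 90 camera calls 37 were kept whichever array was left out. Leaving out 1 array moved the median by over 1.5 times towards 0, or turned it, for 60 of these lists, and away from 0 for 34. That of immediate early genes between maternal diets in control males ran from 3.12e-05 to 0.546 in adjusted p, with its direction turned without control replicate 1 after 18%. The median of acute phase genes between maternal diets in control females turned to -0.0445 without control replicate 2 after 9%.

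Signs of genes not past the threshold also changed with 1 array left out. For the high-fat diet Scd1 ran from -0.11 to 0.25 in females after 18%, Cyp4a14 from -0.16 to 0.54 and Fasn from -0.0818 to 0.79 in females after 9%, and Fasn from -0.14 to 0.40 in males after 9%. For the maternal diet Cyp7a1 ran from -0.000887 to 0.92 in control females. In control males Nr1h3 ran from -0.0212 to 0.0874 and Ppara from -0.13 to 0.31, and in high-fat males Nr1h3 from -0.0670 to 0.21, Ppara from -0.0464 to 0.31, Pck1 from -0.16 to 0.11 and Cyp7a1 from -1.18 to 0.38.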

Other observations

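Of the tests below, those of the hepatocyte share, of a weaker male pattern and of each male array left out in turn were chosen only after the result was seen, and the genes named in the next paragraph were chosen after their values were seen.

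An unnamed probe, ILMN_1230957, rose in males on the high-fat diet. It was detected on 0 of 4 control arrays after maternal 18% and 1 of 4 after 9%, and was at least 14.5-fold and 15.3-fold higher on the high-fat diet (limma adjusted p = 5.60e-05 and 6.27e-05). In females of mothers on 9% other members of the lists also rose on the high-fat diet, among them Apoc2 by 1.15 ± 0.18 (SE, n = 4 per group), Plin5 by 0.75 ± 0.19 and Ppara by 0.55 ± 0.14. Slco1b2, a bile acid transporter, fell by 0.98 ± 0.18, Atp8b1 fell by 0.66 ± 0.17 and C8b fell by 1.03 ± 0.28.

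The male-biased list had medians of -0.54 after maternal 18% and -0.32 after 9% on the high-fat diet in males, where 4 and 0 of 25 genes fell over all genes (camera adjusted p = 1.02e-10 and 4.14e-06; adjusted p = 0.173 and 0.344 with an estimated correlation). A single array as the cause is argued against by the medians without any 1 array of the 2 groups compared. They stayed at -0.503 or lower after 18% (-0.584 without high-fat replicate 1) and at -0.229 or lower after 9% (-0.54 without high-fat replicate 1). Arrays of the other groups cannot move these medians. Array intensity is argued against by -0.553 and -0.35 with it as a covariate, and a lower share of hepatocytes by medians of -0.0805 and 0.01 for hepatocyte markers. As a hypothesis, the high-fat diet may weaken the male pattern of liver expression: the 11 female-biased genes of the same males had medians of 0.534 and 0.55, 1 of them, Cyp17a1, past the threshold. Camera did not call these genes after 18% and called them after 9%, also with raw intensity as a covariate (adjusted p = 0.348 and 0.00153). Cyp4a14 stands in both the female-biased and the fatty acid oxidation list, so these lists are not independent. Against reading these changes as male alone, in females of mothers on 9% Cyp17a1 rose by 1.24 (adjusted p = 0.0145) and the male-biased C8b fell by 1.03. The male-biased list of these females had a median of -0.18 (camera adjusted p = 0.0789), and 2 rose and 5 fell adjusted over the list alone. With raw intensity as a covariate camera called it downwards (median -0.17, adjusted p = 0.0352). In females after 18% the list had a median of 0.0881 (mean -0.0559, camera adjusted p = 0.819), and 0.0432 with the covariate (adjusted p = 0.946). A diet response in both sexes therefore stays open.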
